A study of Escherichia coli BW25113 with 4 samples.

How the data were processed

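Transfer RNA abundance was compared on 4 spotted 2-colour microarrays from Escherichia coli BW25113 lacking hslR, the gene for the heat shock protein Hsp15. Cells carried FLAG-tagged Hsp15 on an arabinose-inducible plasmid. Per the labels, cultures were started at an OD600 of 0.05, induced with 0.00005% arabinose at an OD600 of 0.5, grown at 30 °C to an OD600 of 1.5 and held at 50 °C for 20 min before harvest. RNA from the lysate and from the immunoprecipitated material was deacylated, so that charged and peptidyl tRNAs could be read alike where that step was complete. Its completeness was not tested. Per the labels, 4 pmol of each of 4 in vitro made tRNA standards (human Gln1 and His1, yeast Ala and Phe) went into 5 µg of RNA, and dye-bearing oligonucleotides were ligated to the 3' CCA ends. On 3 arrays, which the labels call biological replicates 1 to 3, Atto635 marked the lysate and Cy3 the Hsp15 immunoprecipitate (IP). On 1 further array, the dye control, both dyes marked lysate. All ratios are Cy3 over Atto635, which is IP over lysate on the 3 IP arrays.

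Per the file headers, each array file holds raw foreground and local background intensity per spot in both channels, with no normalization by the authors. The same deposited files give the percent of a spot's pixels that were saturated or that lay above background plus 2 SD. They also hold a quality score per spot, which per the file headers is a flag and which took the values 0 and -50. Scanner and image software are not given in the sources used here. The authors' deposited value table holds 1 linear ratio per probe for each IP array. Its standards lie near 1. Of its 44 probes, 42 matched a probe on the arrays by name, 38 of them E. coli tRNAs, and the Lys and Tyr probes carry different numbers there and were not matched. On the log2 scale its values correlated with those computed here at r = 0.995, 0.994 and 0.998 when each probe was divided by the dye control, and at 0.981, 0.977 and 0.971 without that division. Its scale and direction were read from this comparison, and the exact formula stays unknown. The median ratio of all its probes was 0.0473, 0.0603 and 0.0799 on replicates 1, 2 and 3. The 1 column of the dye control in that table is empty and was not used.

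Intensities were processed in R 4.3.3 with limma 3.58.1. Median foregrounds were corrected with normexp (offset 50) against the local background median, over all spots. Spots with the code -50 were then left out, as were water and marker spots. The log2 ratios of the spots of a probe were averaged within an array. No loess was applied, because there are few probes, most carry signal and many could shift one way. The array holds 40 E. coli tRNA probes, each spotted 24 times on an IP array and 20 times on the dye control. A probe written Tyr2, without the suffix of the others, was counted among them. Each array was centred either on the mean of its 4 standards or on the median of its 40 tRNA probes. Centring on the standards keeps the tRNA content per amount of RNA labelled. Centring on the median asks whether a tRNA makes up more or less of the IP than of the lysate. Saturated spots were kept, so the lysate signal of the brightest probes is approximate.

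The median tRNA ratio was tested with a two-sided exact sign-flip permutation test over the 3 IP arrays, whose smallest possible p is 0.25. Single probes were tested with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment over the 40 probes at 0.05, for the IP arrays alone and for the IP arrays minus the dye control. In the latter the lone dye control is assumed to vary like the IP arrays. Lists of at least 3 probes, defined by amino acid or by the base that starts the codon, were tested with limma's camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. The files do not pair isoacceptor numbers with anticodons. The list of rare codon readers was therefore not tested, the initiator and elongator Met tRNAs could not be assigned to Met1e and Met2e, and the codon lists leave out Arg, Leu and Ser. Named tRNAs were set by rule: the 4 standards, both Met probes, and, among probes past the threshold with 1 sign on all 3 arrays, the 10 highest and 10 lowest relative to the median tRNA. Groups, tests, lists, this rule and most of the alternatives were fixed before the data were examined. Numbers of tRNA genes per amino acid came from a RefSeq gene table of the MG1655 assembly ASM584v2, and no coordinates are given because the files name no genome build.

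The procedure was tested on simulated data built on the 40 probes, in 100 simulations. Against the median tRNA it recovered 53%, 84% and 98.8% of log2 changes of 0.5, 1 and 2, with 1.68% of unchanged probes called. For IP arrays minus the dye control it recovered 5.75%, 40% and 77.3%, with 0.964% of unchanged probes called. Simulated noise was independent between probes, with no dye preference and no fall of the ratio with lysate signal. On the arrays themselves ratios fell with lysate signal and IP values correlated with those of the dye control. The shares of unchanged probes called therefore do not cover these effects. The number of arrays limits the precision. Alternatives covered background correction, loess, the spot summary, the foreground statistic, spot quality codes, a filter on dim probes, the authors' value table, each replicate and each standard left out, the dye control subtracted, the centring and the moderation. A pair of alternatives, spots above background only and spots without saturated pixels only, was added after the data were seen.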

Results

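The arrays measured how much of each tRNA was present in the Hsp15 IP, relative to the total lysate of the same strain after heat shock. No IP without tagged Hsp15 was analysed here, so tRNA carried over without Hsp15 cannot be told apart. Hsp15 is a heat shock protein that binds the large ribosomal subunit when it carries a peptidyl-tRNA, and the comparison addresses which tRNAs accompany it. There were 3 IP arrays and 1 lysate-against-lysate dye control. The median net lysate signal of the tRNA spots was 7876, 6026 and 22794 intensity units on IP replicates 1, 2 and 3, and 3569 on the dye control. The median net Cy3 signal was 626, 607.5 and 1246 for the IP and 6457 for the lysate on the dye control. Water spots had net Cy3 signals of 5, 11, 30 and 14 on the same 4 arrays. Of the tRNA spots kept, 11.1%, 12.5%, 4.87% and 10.5% were not above background, and 24.1%, 7.33%, 9.31% and 0.507% held saturated lysate pixels. P-values of single probes below rest on the spread between arrays that the labels call biological replicates. Limma shares that spread across probes, fully so in the fit scaled to the standards.

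Scaled to the standards, RNA from the IP held far less tRNA than the same amount of RNA from the lysate. The labels give 5 µg of RNA throughout, so the value is a share of the RNA and does not measure tRNA recovery. The median tRNA had a log2 IP/lysate ratio of -3.73 ± 0.23 (SD, n = 3), 7.53% of the lysate level or 13.3-fold lower. It stood at 6.49%, 8.91% and 7.37% on replicates 1, 2 and 3, and at 102% on the dye control. All 40 tRNAs were lower in the IP, with mean log2 ratios from -4.92 for Asp1e, an aspartate tRNA, to -0.56 for Leu3e, a leucine tRNA. Most Asp1e spots held saturated lysate pixels, so its value is approximate. Leu3e was at 86.6%, 82.1% and 43.7% of its lysate level on replicates 1, 2 and 3. The standards themselves lay between -0.32 ± 0.28 (human His1) and 0.34 ± 0.13 (yeast Phe) on the IP arrays (SD, n = 3), with 0.08 ± 0.22 for human Gln1 and -0.10 ± 0.18 for yeast Ala. On the dye control they lay at -0.14, 0.26, 0.05 and -0.17 in the same order. The two-sided exact sign-flip test of the median tRNA gave p = 0.25, the smallest that 3 arrays allow. Limma called all 40 probes, with the highest adjusted p, 0.0148, for Leu3e. This fit used a single variance for all probes, so the spread of Leu3e itself (SD 0.55, n = 3) does not set its p. The 40 calls are not independent, because the standards of an array shift all its probes together. The Leu3e call was lost without replicate 1 (-0.74, adjusted p = 0.141) and without replicate 3 (-0.25, adjusted p = 0.349). The scale rests on equal amounts of standard in both samples.

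**Figure D1:**
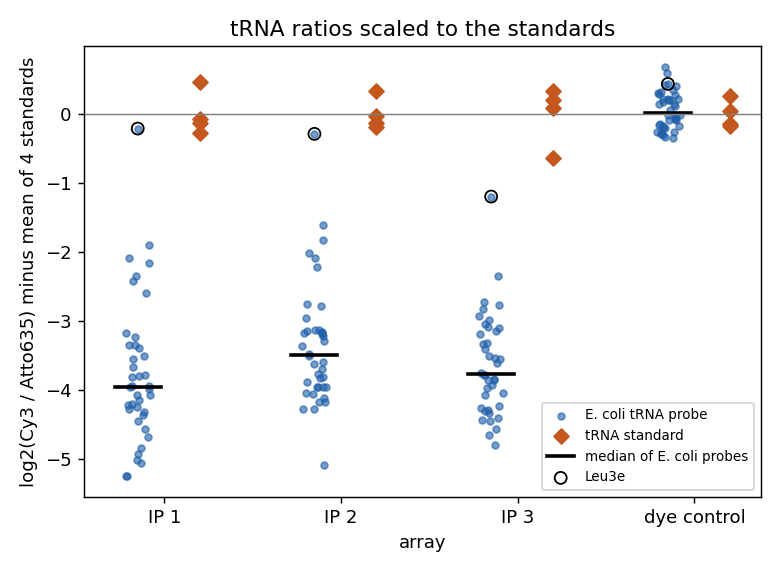
Log2 Cy3/Atto635 ratio of each probe after centring on the 4 standards (vertical axis), for the 3 IP arrays and the dye control (horizontal axis). Small points are the 40 E. coli tRNA probes, the bar is their median, diamonds are the standards and the circle marks Leu3e; the medians of the IP arrays sit at -3.95, -3.49 and -3.76 and that of the dye control at 0.02.

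Composition was compared by setting each tRNA against the median tRNA of its array. Ratios on this scale fell with lysate signal, so faint probes tended to lie high and bright ones low. Spearman's rho with the lysate signal of the other IP arrays was -0.73, -0.77 and -0.59 on replicates 1, 2 and 3. The ranking below is not adjusted for this. The top probe, Leu3e, was among the faintest in the lysate, with net signals of 1323, 1227 and 4885.5 on replicates 1, 2 and 3. Its value under loess was 2.77. Relative to the median tRNA and without loess Leu3e stood apart, 9.00-fold above the median (log2 3.17, SE 0.23, n = 3, limma adjusted p = 0.000144). It was at 3.74, 3.20 and 2.57 on replicates 1, 2 and 3 and 0.41 on the dye control. Leu4e followed at 1.55 (SE 0.27, adjusted p = 0.00433), Met1e at 1.52 (SE 0.16, adjusted p = 0.000991), Lys2e at 1.44 (SE 0.18, adjusted p = 0.00116), His1e at 1.40 (SE 0.17, adjusted p = 0.00116) and Sec1e, the selenocysteine tRNA, at 1.20 (SE 0.22, adjusted p = 0.00502). Leu5e (0.80), Thr2e (0.62), Arg4e (0.59) and Thr1e (0.52) were above the median by less, with adjusted p of 0.0184, 0.00976, 0.00976 and 0.0276. Under loess these 4 were not called (Leu5e 0.38, Thr1e 0.36, Thr2e -0.11 and Arg4e -0.11), while Leu4e (0.71), Lys2e (0.80) and Sec1e (0.60) moved nearer the median with adjusted p of 0.0266, 0.00486 and 0.0179. With saturated spots left out Leu5e, Thr2e, Arg4e and Thr1e, which held none, were not called. Without replicate 1 Leu5e was at 0.51 (adjusted p = 0.0520) and Thr1e at 0.39 (adjusted p = 0.144). Without replicate 2 Thr2e, Arg4e and Thr1e were at 0.58, 0.62 and 0.61 but not called (adjusted p = 0.0753, 0.0598 and 0.0636). With the dye control subtracted Sec1e (0.73), Leu5e (0.45), Arg4e (0.38), Thr1e (0.26) and Thr2e (0.26) were not called, with adjusted p of 0.0613, 0.156, 0.0535, 0.186 and 0.171. In the authors' value table Sec1e (0.67), Leu5e (0.53), Thr1e (0.37) and Thr2e (0.0049) were not called, with adjusted p of 0.117, 0.0791, 0.0679 and 0.978. All of these tRNAs lay below the lysate when scaled to the standards.

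Asp1e had the lowest measured value, 2.28-fold below the median tRNA (log2 -1.19, SE 0.20, n = 3, limma adjusted p = 0.00433). Saturated lysate pixels were found in 95.8%, 91.7% and 83.3% of its spots on replicates 1, 2 and 3. The ratios use median foregrounds, which a few saturated pixels in a spot do not clip. The median net lysate signal of Asp1e was 49060.5 and 41018 on replicates 1 and 2 and 65503.5 on replicate 3. Only the last lay close to the saturated intensity value. Clipping lowers a lysate signal and so raises IP/lysate, so clipping of Asp1e spots would understate its depletion. How far spots of Asp1e and other bright probes were clipped was not tested, so the fold and the rank are approximate. Glu1e, the glutamate tRNA, stood at -0.85 (SE 0.17, adjusted p = 0.00721), Ile1e at -0.85 (SE 0.14, adjusted p = 0.00433), Ser4e at -0.83 (SE 0.19, adjusted p = 0.00971) and Met2e at -0.73 (SE 0.13, adjusted p = 0.00502). The glycine tRNAs Gly1e (-0.72) and Gly2e (-0.61), Gln1e (-0.51) and Pro2e (-0.45) were also below it, with adjusted p of 0.00846, 0.00968, 0.0304 and 0.0308. In all, 21 of 40 probes differed from the median tRNA, 12 higher and 9 lower, and 25 did at an unadjusted p under 0.05. Centring on the mean tRNA instead gave 9 higher and 12 lower, and subtracting the dye control gave 14 calls, 6 higher and 8 lower. That subtraction takes the 1 dye control array as exact, so p-values with the dye control subtracted leave out its error. The fit that counts this error called 1 probe. Against the median tRNA the count was 13 without replicate 2 and 12 with saturated spots left out. Leaving those out favours spots with faint lysate signal, which can raise the ratio of bright probes. Asp1e turned to 0.82 on 7 of 72 spots. It was at 2.70 on replicate 1, where 1 spot, not above background, was left, and at -0.34 and 0.10 on replicates 2 and 3. Glu1e (-0.23), Gly1e (-0.20), Ser4e (-0.43) and Pro2e (-0.28) were not called in that setting, with adjusted p of 0.599, 0.599, 0.185 and 0.406. Under loess Gly1e (-0.33), Gly2e (-0.35), Gln1e (-0.13) and Pro2e (-0.23) were not called, nor were Gly2e (-0.63), Gln1e (-0.38) and Pro2e (-0.40) without replicate 2 or Pro2e (-0.42) without replicate 1. In the authors' value table Glu1e (-0.42), Gly1e (-0.30), Gly2e (-0.48), Gln1e (-0.24) and Pro2e (-0.22) were not called, with adjusted p of 0.0570, 0.0971, 0.0570, 0.210 and 0.252, and with the dye control subtracted Gln1e (-0.35) and Pro2e (-0.31) were not, with adjusted p of 0.118 and 0.0841.

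**Figure D2:**
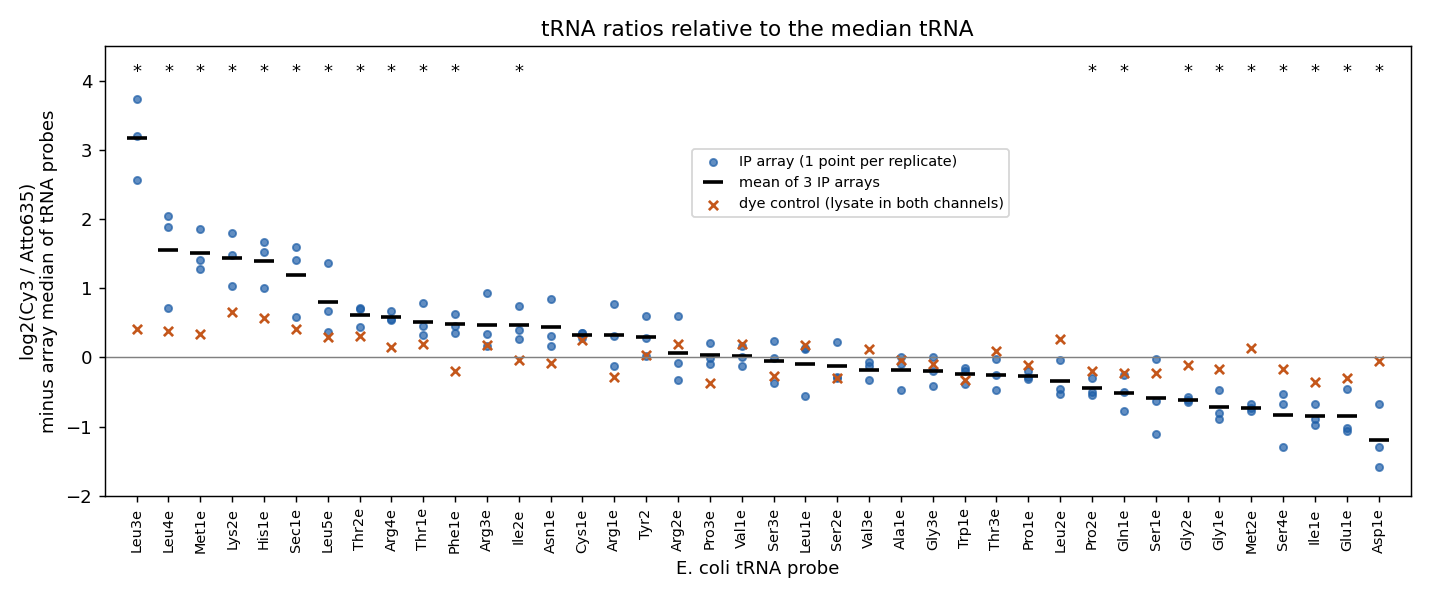
Log2 IP/lysate ratio of the 40 tRNA probes relative to the median tRNA of each array, sorted by mean. Points are the 3 IP arrays, the bar is their mean, the cross is the dye control and an asterisk marks an adjusted p under 0.05 in limma; Leu3e is highest at 3.17 and Asp1e, with mostly saturated lysate spots, lowest at -1.19, and all 40 lie below 0 when scaled to the standards.

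The IP/lysate ratios of isoacceptors of the same amino acid lay apart. Leu3e exceeded Leu2e by 3.51 ± 0.36 on the log2 scale (SD, n = 3), 11.4-fold, against 0.15 on the dye control. Met1e exceeded Met2e by 2.24 ± 0.30, 4.74-fold, against 0.20 on the dye control. Ile2e exceeded Ile1e by 1.31 ± 0.15, 2.49-fold, against 0.32. Highest and lowest isoacceptors were 0.87 ± 0.37 apart for Thr, 0.79 ± 0.13 for Ser, 0.53 ± 0.49 for Arg, 0.52 ± 0.07 for Gly, 0.48 ± 0.27 for Pro and 0.19 ± 0.05 for Val. These differences do not depend on the centring. Each two-sided exact sign-flip test gave p = 0.25, the smallest possible with 3 arrays, except p = 0.5 for Arg. The highest and lowest probe of each amino acid were picked from the same values, and the Gly, Pro, Ser and Ile values are approximate because their lowest probes held saturated lysate pixels. The highest Pro and Ser probes, Pro3e and Ser3e, held them too, in 66.7% and 70.8% of spots on replicate 1. The Pro and Ser gaps could therefore err in either direction. With only unsaturated spots, which favours faint lysate spots, the gap was -0.02 for Gly (n = 2 arrays), 0.12 ± 0.63 for Pro, 0.79 ± 0.21 for Ser and 1.19 ± 0.21 for Ile (SD, n = 3).

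Against the dye control, which carries the dye preference of each probe, Leu3e remained higher by 2.76 (95% interval 1.67 to 3.84, limma adjusted p = 0.0250). The difference was 1.18 (0.40 to 1.97) for Met1e, 1.17 (-0.10 to 2.43) for Leu4e, -0.86 (-1.50 to -0.22) for Met2e and -1.14 (-2.08 to -0.19) for Asp1e, with adjusted p of 0.190, 0.346, 0.213 and 0.254. Dye control values of Lys2e (0.66), His1e (0.57) and Sec1e (0.40) lay on the same side as their IP values, and their differences were 0.77, 0.83 and 0.79. The same held for every other named E. coli tRNA except Met2e (0.13 on the dye control). Among these, Leu3e was at 0.41, Leu4e at 0.39, Met1e at 0.33, Glu1e at -0.30 and Ile1e at -0.36. Glu1e and Ile1e differed from the dye control by -0.55 and -0.49. Leu3e was the 1 probe called, with 6 at an unadjusted p under 0.05. These intervals and p-values assume that the 1 dye control array varies like the IP arrays. The median interval half-width was 0.75, against 0.38 for the IP arrays alone. Without replicate 3, 8 probes were called, 6 higher and 2 lower. Centred on the standards, the Leu3e difference was -1.001.

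Of the 16 lists, the tRNAs that read codons beginning with G lay farthest below the remaining tRNAs. Their mean differed from that of the other tRNAs by -0.81 ± 0.10 (SD, n = 3 arrays), and of 8 probes 4 were lower than the median tRNA (Asp1e, Glu1e, Gly1e and Gly2e), 0 were higher and 4 did not pass, also when adjusted over the list alone. Camera gave p = 0.00576 and adjusted p = 0.0921, and adjusted p = 0.620 with an estimated correlation, and fry gave adjusted p = 0.0294. Ratios fell with lysate signal across probes, which these tests do not take out. Under loess the difference was -0.52 (camera adjusted p = 0.253). Saturated lysate pixels were found in 100%, 65.2% and 83.3% of Gly1e spots and 100%, 54.2% and 83.3% of Glu1e spots on replicates 1, 2 and 3. Leaving out saturated spots removes both from at least 1 array, so the list was not tested evenly that way (difference -0.43 over the 6 probes left, camera adjusted p = 0.661). Readers of codons beginning with A were 5 higher (Met1e, Lys2e, Thr2e, Thr1e and Ile2e), 2 lower (Ile1e and Met2e) and 2 neither, and 6 higher when adjusted over the list alone, with a fry adjusted p of 0.0458 but a camera adjusted p of 0.548, and 0.620 with an estimated correlation. Readers of codons beginning with U were 2 higher and 0 lower of 5, and of those beginning with C 1 higher and 2 lower of 5. These directions are relative to the median tRNA, and all members lay below the lysate when scaled to the standards.

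Of the 5 leucine tRNAs 3 were higher than the median tRNA and 0 lower, with Leu1e at -0.10 and Leu2e at -0.34 (camera adjusted p = 0.548). Threonine had 2 higher and 0 lower of 3, arginine 1 and 0 of 4, glycine 0 and 2 of 3, proline 0 and 1 of 3, and serine 0 and 1 of 4. The 11 tRNAs with a long variable arm (Leu, Ser, Tyr and Sec) had 4 higher and 1 lower, with a median of -0.05 and a mean of 0.45. The 20 tRNAs charged by class I synthetases had 6 higher and 4 lower. By amino acid, 20 nonpolar tRNAs had 6 higher and 5 lower, 8 charged ones 3 higher and 2 lower, and 11 polar uncharged ones 2 higher and 2 lower. The 4 tRNAs with queuosine at the wobble position had 1 higher (His1e) and 1 lower (Asp1e). Median and mean also differed in sign for nonpolar tRNAs (-0.18 and 0.16) and codons beginning with C (-0.27 and 0.04). Apart from codons beginning with A, counts were the same when adjusted over the list alone. Limma's camera called 0 of 16 lists at either correlation, with 1 at an unadjusted p under 0.05. Fry, which tests a list without setting it against other tRNAs, called 4, the others being charged (adjusted p = 0.0294) and queuosine tRNAs (adjusted p = 0.0427), for which camera gave adjusted p of 0.548 and 0.560, and 0.620 for both with an estimated correlation. Directions here are again relative to the median tRNA.

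In the authors' deposited table, whose values lie close to IP over lysate divided by the dye control, Leu3e also had the highest ratio of the E. coli tRNAs, with a mean of 0.487 and values of 0.560, 0.543 and 0.359 on replicates 1, 2 and 3. Mean ratios there were 0.167 for Met1e, 0.132 for Leu4e, 0.112 for His1e, 0.0927 for Sec1e and 0.0315 for Asp1e, and the lowest was 0.0309 for Leu2e. The median tRNA ratio was 0.0405, 0.0592 and 0.0733.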

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

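Tests on the low tRNA content of the IP and on Leu3e were chosen after those results were seen, and tests on the slope against lysate signal before theirs. Marker spots, which no comparison uses, stood out because their net Cy3 signal was 1917, 2447.5 and 2062 on IP replicates 1, 2 and 3, above the 1016.5 of the dye control. Their net Atto635 signal was also higher, at 4651, 1782 and 6884 against 404.5.

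The median tRNA in the IP lay 13.3-fold below the lysate relative to the standards. A difference in dye or labelling between channels is argued against by the dye control, whose median lay 3.51 (log2) above that of the highest IP array. Leaving out any 1 standard kept the shift at or under -3.62, but unequal addition of all 4 standards leaves no trace in such a test and cannot be told apart from a low tRNA content. A low tRNA share of the IP RNA may therefore be real, as a hypothesis. Recovery of tRNA was not measured, because the standards were set against a fixed amount of RNA. No IP without tagged Hsp15 was analysed here.

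Leu3e had the highest IP/lysate ratio on the 3 IP arrays. A dye preference of the probe is argued against by the 2.76 (log2) that remained after the dye control, a single array, was taken off. Additive Cy3 signal of equal size on all probes is argued against too. After the lowest net Cy3 signal of any E. coli probe was subtracted, Leu3e still lay at least 2.63 above the median tRNA. Nonspecific Cy3 signal on the Leu3e probe itself was not tested and stays open. Cross-hybridisation of a standard stays open, because Leu3e lay between the other tRNAs and the standards at -0.56 ± 0.55 (SD, n = 3; -0.25 without replicate 3), and it cannot be told apart from a leucine tRNA that Hsp15 material retains. Such retention may be the source as a hypothesis that was not tested. Without an IP lacking tagged Hsp15, tRNA carried over without Hsp15 cannot be told apart either.

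IP/lysate ratios fell with lysate signal, with slopes of -0.55, -0.43 and -0.48 (log2 ratio per log2 signal, across probes) on IP replicates 1, 2 and 3 and -0.12 on the dye control. Intensity-dependent dye bias of the size seen on the dye control is argued against as the whole cause. Each IP slope lay below that of the dye control, by a difference of -0.306 for the closest. With the dye control subtracted the slope on replicate 3 was -0.16 (SE 0.06). Median net Cy3 signal was 6457 on the dye control against 626, 607.5 and 1246 on the IP arrays. A stronger bias at low Cy3 signal is therefore not excluded. Noise shared through the denominator and Cy3 background at water spots are argued against by slopes of -0.292 against the lysate signal of the other arrays and -0.274 after subtracting the water signal, the shallowest of the 3 arrays each time. Nonspecific Cy3 signal on the tRNA probes themselves was not tested and stays open. Preferential recovery of scarce tRNAs may be proposed as a hypothesis. With gene number as a stand-in for abundance Spearman's rho across amino acids was -0.0013. That value averages isoacceptors, whose ratios lay apart, so it cannot decide the question for single tRNAs.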

How the results depend on the processing

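Spots above background only and spots without saturated pixels only were chosen after the data were seen. The median tRNA stayed far below the standards: -4.13 with loess, -3.97 with the median of spots, -4.04 with mean foregrounds, -4.17 in the authors' value table, -3.50 without saturated spots, and -3.85 to -3.63 with each replicate left out. Against the standards 38 to 40 probes were called, 39 to 40 with a replicate left out, and 21 when centred on the median tRNA. In the authors' value table all 38 matched tRNAs were called. Against the median tRNA, where 21 of 40 probes differed, the count was 13 to 23 with a replicate left out. It was 12 without saturated spots (11 shared, counted whatever their sign) and 40 when centred on the standards. Against the dye control 1 to 8 were called with a replicate left out, 3 with background-subtracted medians, 2 with loess, 2 with mean foregrounds, 3 with an intensity trend and 40 when centred on the standards. Of the lists, 0 to 0 passed camera with a replicate left out, and 4 passed fry. With the dye control subtracted 1 passed camera, codons beginning with G (adjusted p = 0.0253, otherwise 0.0683 to 0.661), but not with an estimated correlation (adjusted p = 0.963). The error of the 1 dye control array is not counted in that setting.

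Under loess Thr2e (-0.11) and Arg4e (-0.11) turned, and without saturated spots Asp1e (0.82), with 7 of 72 spots left. On replicate 1 only 1 Asp1e spot was left, and it was not above background. Leaving out saturated spots favours spots with faint lysate signal. Centring on the standards shifts all probes by a constant, so that Met1e was at -2.22, Leu3e -0.56, Leu4e -2.18, Lys2e -2.29, His1e -2.33, Sec1e -2.54, Leu5e -2.94, Thr2e -3.11, Arg4e -3.14 and Thr1e -3.21, and Leu3e minus the dye control at -1.001. For the shifts under other settings the cause was not tested. Leu3e kept its call under all alternatives run on it that centre on the median tRNA (2.70 to 3.47). Apart from centring on the standards and the filter on dim probes, 256 IP/lysate values of the named tRNAs kept direction and call, 44 lost the call and 3 turned. The filter on dim probes removed 0 probes and tests nothing. The dye control comparison was not run on the value table, whose dye control column is empty. Each IP/lysate ratio compares IP and lysate on the same array. Pairing of the IP arrays with the dye control was not possible because these groups share fewer than 2 replicate numbers. Signal near background limits the faintest spots.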

Other observations

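The test on tRNA gene number was chosen before its result was seen, and the tRNAs and relations described otherwise were picked after their values were seen. Val1e had a mean close to the median tRNA, at 0.01 (SE 0.14, n = 3). The mean of Arg2e, 0.06 (SE 0.20), covered values of 0.60, -0.32 and -0.08 on replicates 1, 2 and 3. Among aromatic amino acids, Phe1e lay at 0.48 (limma adjusted p = 0.0276), while Tyr2 at 0.30 and Trp1e at -0.25 did not pass, with adjusted p of 0.158 and 0.166. Replicate 3 lay nearer the median tRNA for several of the higher tRNAs. Leu4e was at 2.05, 1.88 and 0.72 and Sec1e at 1.60, 1.41 and 0.58 on replicates 1, 2 and 3.

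Across the 40 probes, which are not independent replicates, IP arrays correlated with each other at Pearson r = 0.935, 0.853 and 0.864 and with the dye control at 0.748, 0.652 and 0.563.

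Amino acids with more tRNA genes could be expected to have lower IP/lysate ratios, if abundant tRNAs were retained less. Across 21 amino acids and 86 tRNA genes, Spearman's rho was -0.0013 (permutation p = 0.997, 100000 resamples) and Pearson's r -0.046 (p = 0.843). For IP arrays minus the dye control rho was -0.147 (p = 0.520) and r -0.103 (p = 0.657). All 4 tests had an adjusted p of 0.997. Leu, with 8 genes, lay farthest from the median of 4, and 6 amino acids tied for the next place. Leaving out Leu and each of these in turn gave rho from -0.165 to 0.0071 and r from -0.244 to -0.044, and for IP arrays minus the dye control rho from -0.362 to -0.162 and r from -0.309 to -0.144. No relation was detected across amino acids, and a weak or moderate one is not excluded. Isoacceptors were averaged, so a relation between single tRNAs was not tested.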
